A study of Mus musculus with 2 samples.

How the data were processed

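Total RNA from the heart of 2 adult male B6CASTF1/J mice was sequenced, with 1 library per animal. B6CASTF1/J mice are first-generation offspring of a cross between the C57BL/6J and CAST strains. Per the labels, the animals were 8 to 10 months old, 300 ng of RNA went into each library, ribosomal RNA was reduced, the kit kept strand, and ERCC spike-in RNA was added. The labels name different animals for the 2 libraries but give both the same donor entry. They were treated as 2 animals of 1 group. No second condition exists, so no contrast between conditions was made. An exact sign-flip test over 2 libraries cannot give a two-sided p below 0.5, so no p-value is printed.

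Gene and transcript tables with expected counts, TPM (transcript abundance scaled to a fixed sum per library) and FPKM were deposited for each library, and per the file headers they have the column layout that RSEM writes. The transcript tables also hold the percent share of each transcript in its gene, as deposited. A separate transcript table per library, here called the second quantification, gives estimated counts and TPM in the column layout that kallisto writes, per the file headers. Per the file listings deposited with each library, all tables use the mm10 assembly and GENCODE M21. The versions of the quantification tools and the aligner are not given in the sources used here. In the deposited RSEM-layout transcript tables the effective length is the transcript length less 100 nucleotides, for 100% of transcripts with an effective length above 0. In the second quantification the median difference was 249 nucleotides in replicate 1 and 248 in replicate 2, among transcripts over 1 kilobase. This raises short RNAs by different amounts in the 2 quantifications. Because of that fixed sum, a few abundant RNAs lower the TPM of all others.

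The gene tables hold 55536 mouse gene rows, 96 ERCC rows, a phiX row and 26248 rows with numeric identifiers. The numeric rows held 1 expected count in replicate 1 and 0 in replicate 2, were not identified, and were left out. Total expected counts were 42.13 M in replicate 1 and 40.07 M in replicate 2, of which 99.8% lay on mouse genes in each. Gene symbols, types and positions came from GENCODE M21, with 1-based coordinates on mm10. Expected counts were rounded to whole numbers before any count-based step. The chi-square of the 2 libraries' counts was 15.4 per degree of freedom over 17075 genes with 10 or more summed counts, so the libraries differed by more than sampling noise and were not a single library deposited 2 times.

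Each level is given as the mean ± SD of TPM over 2 libraries. The level of a gene list is the median over its members in each library, given as the mean ± SD of the 2 medians. Libraries were scaled with the TMM method of edgeR 4.0.16 over genes without spike-ins. A gene was counted as differing between the 2 animals when its counts summed to 200 or more, its scaled ratio was at least 2-fold and the exact Clopper-Pearson 99.9% interval of the ratio excluded 1. These intervals, and the 95% exact binomial intervals of shares, cover counting error only. Reads carry no molecular identifiers in these tables, so amplified copies cannot be told from independent molecules. A count of 0 was replaced by a floor of 3 counts in that library, and the ratio is then an estimate whose counting interval can start lower. The biological coefficient of variation was the square root of the common dispersion from edgeR, with an intercept-only model after its filter on low counts. For gene lists, the median log2 ratio of replicate 2 over replicate 1 was taken over members with 50 or more summed counts. It is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, for lists with at least 4 such members. That percentile describes these 2 libraries and no condition. Work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and in R 4.3.3 with DESeq2 1.42.0 for an alternative scaling and dispersion.

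The steps were tested on simulated counts drawn from the real genes' means and library sizes, with 10960 genes at 200 or more summed counts. With a simulated coefficient of variation of 0.1, the rule for differing genes called 100% of genes changed 3-fold or 4-fold, 46% of those changed 2-fold, 2% of those changed 1.5-fold, and 0 unchanged genes. The 99.9% counting interval then held the true ratio for 71.7% of genes, since it leaves out variation between animals. Of 100 unchanged lists of 12 genes, 3 lay outside the central 95% of random lists, and 92 of 100 lists shifted by 0.3 (log2) lay above it. Simulated coefficients of 0.1 and 0.3 were estimated as 0.098 and 0.296.

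Before the data were examined, 41 gene lists, 22 gene pairs, 16 genes for isoform shares and the rule for naming genes were fixed. The rule names the 20 nuclear protein-coding genes with the highest mean TPM and up to 4 members of each list by mean TPM. It also names the highest member of lists for tissues outside the heart, all pair and isoform genes, and the 8 most abundant genes that are neither protein-coding nor mitochondrial. Between the animals it names the 12 protein-coding or long noncoding genes with the largest ratio in each direction. Sex-linked genes, Nnt, H2-K1 and H2-D1 were also named. Results for some genes that the rule names are not reported here. Of the list members, 628 matched a gene in M21 and 1 did not (Norad). A nuclear pseudogene was counted as sharing sequence with mitochondrial mRNAs when at least 10% of its 31-mers occurred in them. For 86 of the 55536 genes, no row of the second quantification was used here, which left 55450 genes for correlations between the quantifications.

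Alternatives covered other detection thresholds, FPKM, counts in place of TPM, the second quantification, 4 other scalings, other filters and fold thresholds, other dispersion estimates, and leaving out each library. Sequence reads and allele-specific counts were not analysed here, so differences between the C57BL/6J and CAST alleles against the mm10 reference remain unmeasured.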

Results

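Total RNA sequencing of the heart of 2 adult male B6CASTF1/J mice gave 42.05 M expected counts on mouse genes in replicate 1 and 39.98 M in replicate 2. The labels call these animals 2 and 4. The series holds a single group, so the report describes which genes and cell types the hearts expressed and how far the 2 animals differed. In what follows ± is the SD over 2 libraries (n = 2) unless stated otherwise. At least 1 TPM was reached in both libraries by 11607 genes, of which 10768 were protein-coding, 300 long noncoding and 397 pseudogenes.

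The most abundant nuclear mRNAs encoded the contractile apparatus, oxygen handling and oxidative metabolism of heart muscle. Myl2, the ventricular regulatory myosin light chain (ENSMUSG00000013936.12, mm10 chromosome 5, 122100951 to 122113472), stood first at 7983 ± 458 TPM (14096 in the second quantification). Mb, encoding the oxygen-binding protein myoglobin, followed at 7736 ± 213 TPM. Myh6, the alpha myosin heavy chain (ENSMUSG00000040752.16, chromosome 14, 54941921 to 54966927), reached 6638 ± 443 TPM, and Actc1, cardiac actin, 5014 ± 385 TPM. Atp2a2, the calcium pump of the sarcoplasmic reticulum (ENSMUSG00000029467.15, chromosome 5, 122453513 to 122502225), was at 4428 ± 286 TPM, and its inhibitor Pln at 2914 ± 159 TPM. Other sarcomere genes among the first 20 were Myl3 (4011 ± 229 TPM), Tpm1 (3450 ± 257), Tnni3 (3438 ± 210), Tnnt2 (3217 ± 167) and Tnnc1 (2152 ± 158). Energy metabolism was represented by Atp5b (3213 ± 113 TPM), Fabp3 (2647 ± 57.2), Gapdh (2018 ± 4.53), Cox4i1 (1662 ± 45.4), Cox6b1 (1604 ± 105) and Slc25a4 (1593 ± 72.3). The hemoglobin genes Hbb-bs (3251 ± 1384 TPM), Hba-a1 (2996 ± 1240) and Hba-a2 (2420 ± 1001) completed the 20 and had the largest SDs among them. Hba-a1 and Hba-a2 are near-identical copies, so the split of reads between them is uncertain, and the second quantification gave 4810 and 1372 TPM.

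**Figure D1:**
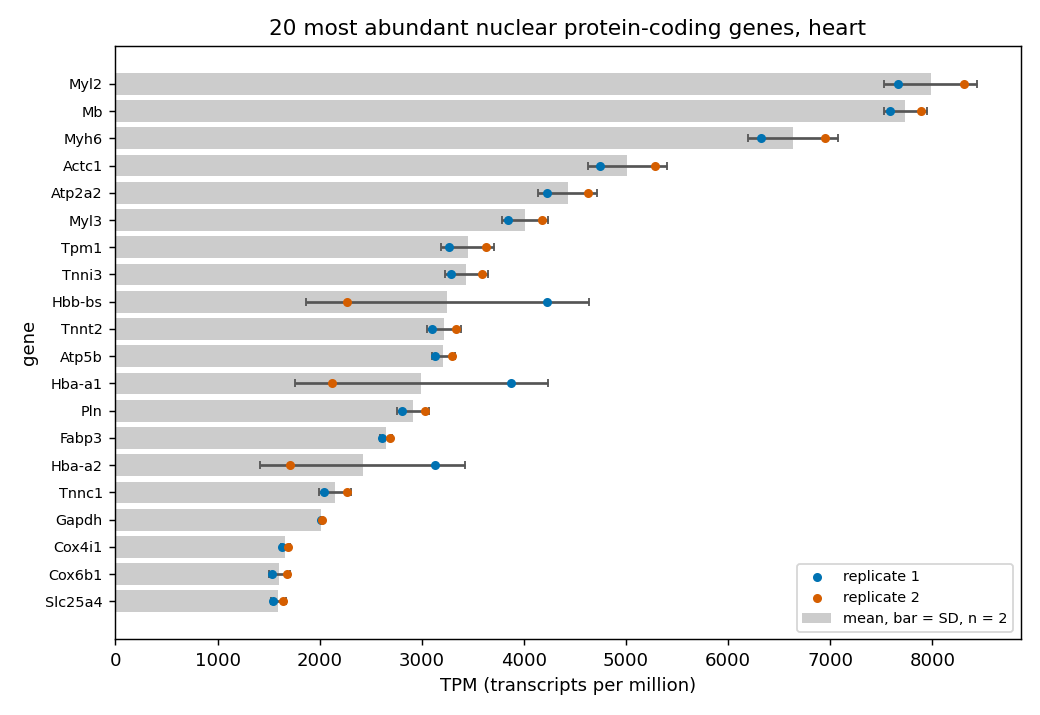
TPM of the 20 most abundant nuclear protein-coding genes, with grey bars for the mean, error bars for the SD (n = 2) and points for each library. The 3 hemoglobin genes have the widest error bars, with Hbb-bs at 4229 TPM in replicate 1 and 2272 TPM in replicate 2.

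Transcripts from the mitochondrial genome made up a large part of the RNA sequenced, after ribosomal RNA had been reduced per the labels. The 13 mitochondrial mRNAs held 15.9 ± 0.826% of all TPM and the mitochondrial ribosomal RNAs a further 20.4 ± 0.698%. Among the mRNAs, mt-Co1 reached 38676 ± 1035 TPM, mt-Co3 36166 ± 1826, mt-Cytb 17004 ± 1136 and mt-Atp6 16809 ± 1475. Nuclear pseudogenes on chromosome 1 that share sequence with these mRNAs held another 6.91 ± 0.112% of TPM, led by Gm28661 (33504 ± 1376 TPM), Gm29216 (21798 ± 63.1) and Gm10925 (13108 ± 460). These lie side by side between 24613974 and 24616197. All 31-mers of Gm28661 and Gm10925 and 97.2% of those of Gm29216 occur in mitochondrial mRNAs, so the division of reads between the 2 genomes is uncertain. In the second quantification mt-Co3 stood at 14286 TPM, mt-Atp6 at 29262, Gm29216 at 1681 and Gm10925 at 60.9. Gm28437, whose 31-mers all occur in mitochondrial mRNAs, went from 0.190 to 21404 TPM.

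Noncoding RNAs, most of them small structural RNAs, were also abundant. The RNA component of the signal recognition particle, encoded by the identical copies Rn7s1 and Rn7s2, held 16.2 ± 0.779% of TPM but 2.67 ± 0.143% of expected counts, since both are short. Rn7sk, a regulator of transcription elongation, was at 7211 ± 308 TPM and Rpph1, the RNA of ribonuclease P, at 2403 ± 110. The longer Gm26917, annotated as a lincRNA (chromosome 17, 39843013 to 39846341), was at 4619 ± 159 TPM. Together the 100 most abundant genes held 73.1 ± 0.435% of TPM. Spike-in RNA held 0.203% of counts in replicate 1 (exact 95% interval 0.202 to 0.204%) and 0.213% in replicate 2 (0.211 to 0.214%), with 60 and 59 of the 96 spike-ins read.

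Contraction genes were present throughout. All 25 sarcomere and cytoskeleton genes passed 1 TPM in both libraries, with a list median of 695 ± 35.4 TPM. All 16 calcium handling genes did so as well (median 141 ± 2.84 TPM). After Atp2a2 and Pln the highest were S100a1 (392 ± 19.95 TPM) and Hrc (376 ± 23.6), while the release channel Ryr2 was at 367 ± 12.6 TPM. The 21 ion channels and pumps had a median of 22.6 ± 7.83 TPM, with the gap junction gene Gja1 (148 ± 8.46) and the sodium pump subunit Atp1b1 (119 ± 13.5) among the highest. All 19 cardiac transcription factors were read (median 25.8 ± 2.27 TPM), with Esrra (58.6 ± 2.05), Mef2a (50.9 ± 2.26), Gata4 (46.9 ± 5.73) and Mef2d (46.5 ± 4.47) the highest.

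The lists for fatty acids, the tricarboxylic acid cycle, oxidative phosphorylation and glycolysis had medians between those of calcium handling and sarcomere genes. The 23 fatty acid genes had a median of 336 ± 10.2 TPM, led by Fabp3, Lpl (1336 ± 41.9), Hadhb (986 ± 14.2) and the fatty acid transporter Cd36 (705 ± 6.80). The 20 tricarboxylic acid cycle genes had a median of 262 ± 14.6 TPM, with Ogdh (704 ± 33.6), Mdh2 (698 ± 31.1) and Sdha (477 ± 18.9) among the highest. The 32 nuclear subunits of oxidative phosphorylation had a median of 489 ± 18.96 TPM, led by Atp5b, Cox4i1, Cox6b1 and Atp5a1 (1432 ± 70.1). Glucose uptake and glycolysis genes had a median of 182 ± 7.26 TPM, with Gapdh, Aldoa (1451 ± 10.1), Ldhb (1263 ± 106) and Eno3 (626 ± 50.3) the highest and 19 of 20 members above 1 TPM in both libraries. In the creatine kinase system (median 60.4 ± 0.530 TPM), Ckm (1305 ± 111 TPM) and Ckmt2 (929 ± 62.2) exceeded Slc6a8 (60.4 ± 0.530) and Ckb (24.6 ± 0.0283).

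Both atrial and ventricular tissue were represented. The 10 atrial markers all passed 1 TPM (median 23.5 ± 2.91), led by Nppa (569 ± 66.7), Myl4 (234 ± 19.8), Myl7 (171 ± 17.3) and Sln (29.3 ± 5.37). Of the 7 ventricular markers (median 12.7 ± 2.12 TPM), Myl2 and Myl3 were followed by Kcnip2 (63.7 ± 0.219) and Irx4 (12.7 ± 2.12). Conduction system markers were low, with a median of 1.42 ± 0.0354 TPM and 6 of 11 above 1 TPM in both, led by Smoc2 (16.04 ± 0.580), Cacna2d2 (5.09 ± 0.346), Tbx3 (3.41 ± 0.148) and Cacna1g (3.37 ± 1.48). The pacemaker channel gene Hcn4 was at 2.76 ± 0.368 TPM. Cardiac stress genes had a median of 62.4 ± 14.7 TPM and after Nppa were led by Myh7 (521 ± 21.01), Ankrd1 (398 ± 52.1) and Acta1 (194 ± 17.5).

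In 21 of 22 gene pairs the gene listed first, in most cases the heart or adult form, was the higher in both libraries. The log2 ratio of Myh6 to Myh7 was 3.67 ± 0.0381, or 12.7-fold, against 7.50-fold in the second quantification and a log2 ratio of 4.52 from expected counts. That of Actc1 to skeletal Acta1 was 4.69 ± 0.0196, and that of Tnni3 to the fetal form Tnni1 13.84 ± 0.0446. Wide gaps were also seen for Tnnc1 over Tnnc2 (11.09 ± 0.158) and Atp2a2 over Atp2a1 (10.80 ± 0.00522). Myl2 exceeded the atrial chain Myl7 by 5.55 ± 0.0636 and Myl3 exceeded Myl4 by 4.10 ± 0.0400. Pln exceeded Sln by 6.65 ± 0.187, Gja1 exceeded Gja5 by 4.74 ± 0.230 and Nppa exceeded Nppb by 2.68 ± 0.479. Metabolic pairs followed with Ckm over Ckb (5.72 ± 0.125), Slc2a4 over Slc2a1 (5.14 ± 0.242), Eno3 over Eno1 (3.91 ± 0.149), Cpt1b over Cpt1a (3.88 ± 0.157) and Pgam2 over Pgam1 (3.04 ± 0.354). Ldhb exceeded Ldha by 2.09 ± 0.139, and Esrra exceeded Esrrg by 1.66 ± 0.179. The muscle forms of cytochrome oxidase subunits led as well, with Cox6a2 over Cox6a1 (3.40 ± 0.0322), Cox8b over Cox8a (2.84 ± 0.0182) and Cox7a1 over Cox7a2 (1.87 ± 0.0537). Other pairs whose fold moved by over 1.5 times in the second quantification, given as log2 ratios, were Myl2 over Myl7 (6.31) and Tnnc1 over Tnnc2 (10.43). From expected counts, which are not corrected for length, those that did were Ldhb over Ldha (1.41), Pgam2 over Pgam1 (1.87), Esrra over Esrrg (0.81), Cox7a1 over Cox7a2 (1.12), Cox8b over Cox8a (2.05) and Tnni3 over Tnni1 (12.99). With a pseudocount of 1, Tnni3 over Tnni1 was at 11.44 and Tnnc1 over Tnnc2 at 10.08. The exception to the order of the pairs was Kcnj2, which was lower than the atrial potassium channel gene Kcnj3 at -1.07 ± 0.0972.

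Isoform shares depended on the quantification for several genes. The leading transcript held over 50% of its gene in both libraries for 7 of 16 genes. In both quantifications the leading transcript was the same for 12 genes, among them Atp2a2 (Atp2a2-202, 77.4 ± 0.262%, against 79.6% in the second quantification), Ldb3 (Ldb3-203, 68.8 ± 1.83% against 68.5%), Tpm1 (Tpm1-205, 97.2 ± 0.148% against 64.9%) and Myh6 (Myh6-201, 56.3 ± 0.530% against 64.3%). Also the same were those of Ttn (Ttn-201, 39.2 ± 0.912%), Pkm (Pkm-201, 51.5 ± 0.460%), Camk2d (Camk2d-202, 48.4 ± 3.45% against 30.2%), Mef2d (Mef2d-201, 50.9 ± 5.08%) and Nebl (Nebl-202, 32.2 ± 0.608%). Fhod3-201 held 43.6 ± 1.16% in RSEM and 94.1% in the second quantification, and Nnt-202 51.6 ± 1.37% and 89.9%. The Nnt shares are of unlike totals. The second quantification also placed transcripts on another Nnt gene model, which its share leaves out. Bin1-205 held 93.7% in replicate 1 and 43.04% in replicate 2, the widest gap between animals of the 16. The leading transcript differed between quantifications for Tnnt2, Slc8a1, Cacna1c and Mef2c. For Tnnt2, Tnnt2-211 led in RSEM with 75.4 ± 0.863% but held 3.74% in the second quantification, where Tnnt2-212 led with 49.3%. RSEM led with Slc8a1-202 (38.6 ± 0.771%, against 4.24% in the second quantification), Cacna1c-218 (36.6 ± 1.06%, against 20.6%) and Mef2c-212 (21.2 ± 1.11%, against 21.5%). Of these, Cacna1c-218 is annotated as a processed transcript and not as protein-coding.

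The following lists for cell types other than heart muscle cells had medians below those of sarcomere and calcium handling genes. The endothelial median was above those of cardiac transcription factors, ion channels and pumps, and atrial and ventricular markers. The fibroblast and matrix median was also above that of ventricular markers. Endothelial markers had a median of 36.6 ± 3.76 TPM, led by Fabp4 (186 ± 5.37), Aqp1 (120 ± 1.53), Ly6c1 (74.1 ± 9.33) and Egfl7 (48.8 ± 0.948). Fibroblast and matrix genes had a median of 17.96 ± 0.0530 TPM, led by Gsn (214 ± 15.4), Dcn (112 ± 12.4), Fn1 (45.9 ± 50.4) and Col3a1 (33.7 ± 5.35). Mural markers were headed by Rgs5 (106 ± 1.22), Acta2 (24.5 ± 4.42), Tagln (16.6 ± 5.45) and Pdgfrb (9.22 ± 2.11), with a median of 7.998 ± 0.633 TPM. Lymphatic endothelial markers had a median of 3.75 ± 0.714 TPM, with Ccl21a (19.3 ± 0.00707), Prox1 (18.3 ± 5.11), Flt4 (4.37 ± 0.163) and Lyve1 (4.04 ± 1.13) the highest. Prox1 is also expressed in heart muscle cells. Macrophage markers had a median of 3.13 ± 0.0389 TPM, with Lyz2 (58.7 ± 41.7), C1qb (10.9 ± 0.530), Csf1r (9.91 ± 0.304) and C1qa (9.15 ± 1.32) on top. Epicardial and mesothelial markers had a median of 2.17 ± 1.13 TPM, led by Msln (5.22 ± 1.94), Upk3b (5.05 ± 1.48), Aldh1a2 (2.51 ± 1.26) and Krt19 (2.29 ± 1.09).

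Blood, nerve and fat markers were low apart from the hemoglobins. Erythroid genes together held 0.899 ± 0.378% of TPM, and Hbb-bt, at 289 ± 138 TPM, was the median of the list, against 537 TPM in the second quantification. Platelet markers had a median of 4.63 ± 1.90 TPM, led by Pf4 (10.9 ± 2.60), Ppbp (7.23 ± 3.13), Itga2b (2.02 ± 0.679) and Gp9 (0.760 ± 0.693). Lymphocyte, neutrophil, adipocyte, and Schwann cell and neuron lists had medians of 0.295 ± 0.233, 0.660 ± 0.636, 0.780 ± 0.651 and 0.478 ± 0.110 TPM. Lymphocyte reads came mostly from Ighm (3.73 ± 0.820), Igkc (2.02 ± 1.56), Cd79b (0.655 ± 0.219) and Cd79a (0.495 ± 0.346). The highest neutrophil markers were S100a9 (2.43 ± 2.39), S100a8 (1.37 ± 1.61), Csf3r (1.04 ± 1.17) and Retnlg (0.680 ± 0.608). For adipocytes they were Cidea (15.2 ± 1.54), Cfd (3.36 ± 2.70), Cidec (1.23 ± 1.07) and Plin1 (1.01 ± 0.976), and those for Schwann cells and neurons included Uchl1 (3.24 ± 0.311), Mbp (2.24 ± 0.636) and S100b (0.740 ± 0.170). Lists for tissues outside the heart were headed by Myl1 for fast skeletal muscle (14.4 ± 0.113 TPM), Scgb1a1 for lung epithelium (7.80 ± 11.0), Ttr for hepatocytes (0.315 ± 0.00707) and Themis for thymocytes (0.115 ± 0.0212). The 355 and 346 reads of Myl1 were even between the animals.

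State-dependent genes were mostly at moderate levels. Heat shock and chaperone genes had a median of 60.5 ± 14.3 TPM (Hspa8 482 ± 135, against 725 in the second quantification, Hspa5 222 ± 18.8, Hspb1 138 ± 40.7, Hspd1 126 ± 0.919). Fasting and glucocorticoid genes had a median of 15.8 ± 0.0672 TPM (Txnip 236 ± 18.5, Pdk4 153 ± 34.6, Mt1 63.7 ± 8.37, Tsc22d3 40.5 ± 5.51). For immediate early genes it was 6.20 ± 3.63 TPM (Ccn1 29.2 ± 1.15, Dusp1 17.7 ± 8.25, Klf2 16.6 ± 7.17, Jun 15.0 ± 5.07). Clock genes of the E-box and D-box phase had a median of 14.6 ± 4.35 TPM (Usp2 64.3 ± 12.4, Tef 48.6 ± 7.10, Dbp 40.5 ± 21.8, Nr1d1 39.7 ± 4.47), and those of the Bmal1 phase 3.19 ± 0.113 (Clock 9.94 ± 0.198, Nfil3 6.02 ± 3.14, Cry1 3.10 ± 0.233, Arntl 2.56 ± 0.785). Interferon response genes had a median of 1.15 ± 0.00707 TPM (among them Bst2 4.96 ± 0.389, Irgm1 4.54 ± 0.120, Gbp2 4.09 ± 0.318). None of the 10 cell cycle genes passed 1 TPM in both libraries (Mki67 0.790 ± 0.0566, Top2a 0.730 ± 0.566, Cdk1 0.380 ± 0.0849, Tpx2 0.365 ± 0.0354). Ribosomal protein genes had a median of 153 ± 1.04 TPM (Rpl41 461 ± 5.40, Rps29 441 ± 6.60, Rps27 380 ± 17.5, Rps14 353 ± 12.4). Replication-dependent histones had one of 2.83 ± 0.926 (Hist1h4h 84.9 ± 6.27, Hist2h2aa2 83.5 ± 4.73, Hist1h1c 63.7 ± 8.24, Hist1h2bc 27.7 ± 1.33). The long noncoding RNAs had one of 1.57 ± 0.106, led by Malat1 (553 ± 68.5, against 303 in the second quantification), Neat1 (37.5 ± 3.89), H19 (19.7 ± 9.03) and Gas5 (17.4 ± 0.827).

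The Y-linked genes Ddx3y (21.5 ± 0.382 TPM), Eif2s3y (19.2 ± 2.54), Uty (6.27 ± 0.148) and Kdm5d (3.43 ± 0.912) were read in both animals, while Xist had 3 and 1 reads. Nnt, which carries a deletion in C57BL/6J, was read at 21601 and 21652 counts (ENSMUSG00000025453.18, chromosome 13, 119335448 to 119408997), with 0 counts on another Nnt gene model. Its level was 201 ± 8.99 TPM, against 84.1 in the second quantification, which gave the other model 97.2 TPM. H2-K1 stood at 48.0 ± 12.4 TPM and H2-D1 at 49.3 ± 13.7 TPM. Both genes vary between strains, and the loss of CAST reads against the mm10 sequence was not analysed here.

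Between the 2 animals most genes were close. Among 10960 genes with 200 or more summed counts, the median absolute log2 ratio was 0.11. The biological coefficient of variation was 0.121 over 14694 genes. The rule for differing genes was met by 118 genes, of which 94 were higher in replicate 1 and 24 in replicate 2. Of the 118, 94 also met it in the second quantification in the same direction (78 and 16). With 1 library per animal these differences have no replicate check.

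Among protein-coding and long noncoding genes, with counts of 0 set to the floor of 3, the largest ratios toward replicate 1 were those of Alox15, Chil3, Bpifa1 and Slpi. Alox15, encoding a lipoxygenase of resident serosal macrophages and eosinophils (ENSMUSG00000018924.6, chromosome 11, 70344152 to 70352031), had 2230 counts in replicate 1 and 1 in replicate 2 (2149-fold, counting interval 214 to 4.30e+06). Chil3, a chitinase-like protein of macrophages (chromosome 3, 106147554 to 106167564), had 1574 and 2 counts (758-fold, 125 to 47502). Bpifa1 (chromosome 2, 154142880 to 154149219) and Scgb1a1 (chromosome 19, 9083636 to 9087958), both secreted by airway epithelium, had 682 and 204 counts against 0. Against the floor of 3 counts the ratios were 219-fold and 65.5-fold, so the rank of both genes depends on that floor. Their counting intervals start at 85.98-fold and 25.4-fold. Slpi, a secreted protease inhibitor, had 806 and 6 counts (129-fold, interval 40.4 to 806). Csf2rb, a cytokine receptor subunit, was 14.9-fold higher (6.44 to 44.1), the adhesion gene Selp 13.6-fold (6.44 to 34.8), coagulation factor F5 12.7-fold (9.03 to 18.4), the haptoglobin gene Hp 9.64-fold (4.58 to 24.1) and Fos 7.97-fold (5.22 to 12.7). Gm28635 (538 and 43 counts) and Mrpl23 (219 and 22) also ranked here, but their log2 ratios of -3.59 and -3.26 became -0.98 and -0.03 in the second quantification. Scgb1a1 did not reach the count minimum in the second quantification, where its log2 ratio was -5.29.

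Among protein-coding and long noncoding genes, the largest ratio toward replicate 2 was 4.49-fold. It was that of Snai3, a zinc finger repressor (interval 2.78 to 7.63), Hs3st5, a heparan sulfate sulfotransferase, 2.95-fold (1.80 to 5.05), and the mitochondrial uncoupling protein gene Ucp3 2.87-fold (2.44 to 3.38). Gadd45b (2.64-fold), Frem2 (2.52-fold), Akap5 (2.51-fold), Foxo6 (2.45-fold), Map2k6 (2.37-fold), Sv2a (2.36-fold), Rrad (2.27-fold) and Zc3h6 (2.27-fold) completed the set together with Gm2004. Rrad, a small GTPase that inhibits calcium channels, had the most reads (3648 and 7984 counts). Gm2004 was 2.43-fold higher, but its log2 ratio of 1.28 became 0.06 in the second quantification.

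**Figure D2:**
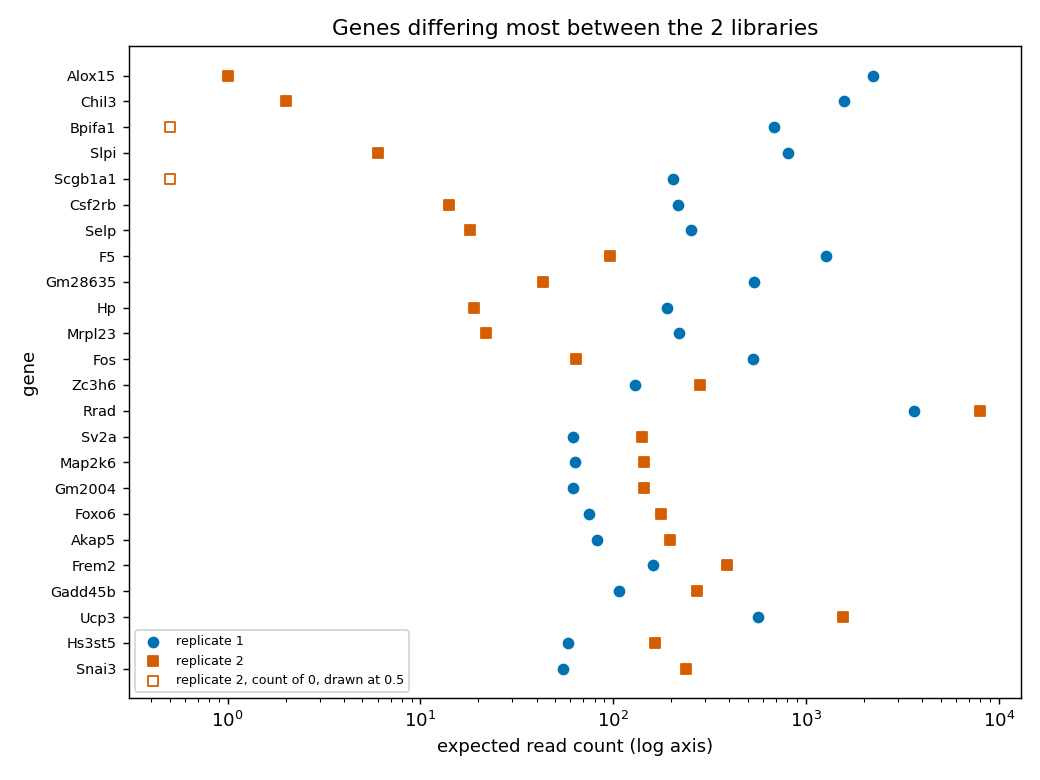
Expected read counts (log axis) of the 24 protein-coding or long noncoding genes with the largest ratios between the 2 libraries, 12 in each direction, circles for replicate 1 and squares for replicate 2, with open symbols at 0.5 for a count of 0. The upper 12 genes are higher in replicate 1, up to 2230 counts against 1 for Alox15, and the lower 12 are higher in replicate 2 by up to 4.49-fold.

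Of the 35 lists with enough members, 19 lay outside the central 95% of random lists. If list members varied independently of each other, 1.75 lists would lie outside. Members of a list can move together and some lists share members, so the 19 are not separate results. Below the central 95% were 12 lists, each with a negative median log2 ratio, that is, toward replicate 1. By median TPM, the fasting and glucocorticoid list (15.78 and 15.875) and the ribosomal protein list (151.77 and 153.24) were slightly higher in replicate 2. Immediate early genes had a median log2 ratio of -1.05 (percentile 0), with 19 of 19 members lower in replicate 2 and 7 meeting the rule for differing genes. Heat shock and chaperone genes had one of -0.65 (percentile 0), 10 of 10 lower, with Hspa1a at -1.84 and Hsp90aa1 at -0.86. Fasting and glucocorticoid genes were at -0.33 (percentile 0), 10 of 12 lower, with Cdkn1a at -1.68 and, in the other direction, Ucp3 at 1.52. Cardiac stress genes were at -0.29 (percentile 0.01), 5 of 8 lower and 3 higher in replicate 2, with Ccn2 at -1.02 and Nppa at 0.21. Their median was -0.11 (percentile 0.66) when members needed 200 summed counts, and -0.46 in the second quantification.

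Blood, fat and surface cells moved in the same direction. Erythroid genes had a median log2 ratio of -0.94 (percentile 0), with Hbb-bs 1.90-fold higher in replicate 1 (1.86 to 1.93). For the adipocyte list it was -2.02 (percentile 0), with Lep at -3.41, Ucp1 at -3.05 and Cidea at -0.24. The epicardial and mesothelial list lay at -0.81 (percentile 0), 8 of 8 lower in replicate 2, with Wt1 at -1.26 and Msln at -0.72. Endothelial genes were at -0.13 (percentile 0.01). Of the adipocyte members, 1 reached 200 summed counts, as did 1 of the cell cycle genes. Cell cycle genes were at -0.84 (percentile 0.75) over 5 members, long noncoding RNAs at -0.27 (percentile 0.05), replication-dependent histones at -0.28 (percentile 0) and ribosomal protein genes at -0.04 (percentile 0.05). The histone list ran the other way, at 0.08 and within the central 95%, when members needed 200 summed counts.

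Lists above the central 95% were mostly those of muscle cells. Clock genes of the E-box and D-box phase had a median log2 ratio of 0.34 (percentile 100), with 11 of 12 members higher in replicate 2, Dbp at 1.13 and Bhlhe41 at 0.82. Atrial markers were at 0.18 (percentile 99.99), 10 of 10 higher. Ion channels and pumps were at 0.13, cardiac transcription factors at 0.11, mitochondrial mRNAs at 0.11, sarcomere genes at 0.08 and calcium handling genes at 0.08. Their percentiles were 98.7 or more. In that order, 17 of 21, 13 of 19, 11 of 13, 17 of 25 and 14 of 16 members were higher in replicate 2. Under spike-in scaling the sarcomere and calcium handling medians were 0.035 and 0.033.

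The macrophage list as a whole did not stand apart (median log2 ratio 0.01, percentile 56.3), because its members went both ways. Lyz2 at -1.62 and Adgre1 at -1.35 met the rule for differing genes, while C1qb was at 0.07, Csf1r at -0.10 and Mrc1 at 0.37. Neutrophil and lymphocyte lists had too few members for this comparison, with medians of 1.11 and 0.460 TPM in replicate 1 and 0.210 and 0.130 in replicate 2. The fibroblast and matrix list also stayed inside (0.01, percentile 35.8), although its member Fn1 was at -2.95 (14731 and 1834 counts). The other lists inside the central 95% were those for ventricular markers (0.09), conduction system (0.04), fatty acids (0.04), glycolysis (0.01), the tricarboxylic acid cycle (0.06), nuclear oxidative phosphorylation (0.05), creatine kinase (0.06), lymphatic endothelium (-0.03), mural cells (0.08), Schwann cells and neurons (-0.19), fast skeletal muscle (0.10), the Bmal1 phase of the clock (-0.07), interferon response (-0.11) and sex-linked genes (0.13). Of these, the signs of the fatty acid, glycolysis, macrophage, fibroblast and conduction system medians flip under spike-in scaling, and those of the interferon response and lymphatic endothelial medians flip in the second quantification. None of these 7 is read as a direction.

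**Figure D3:**
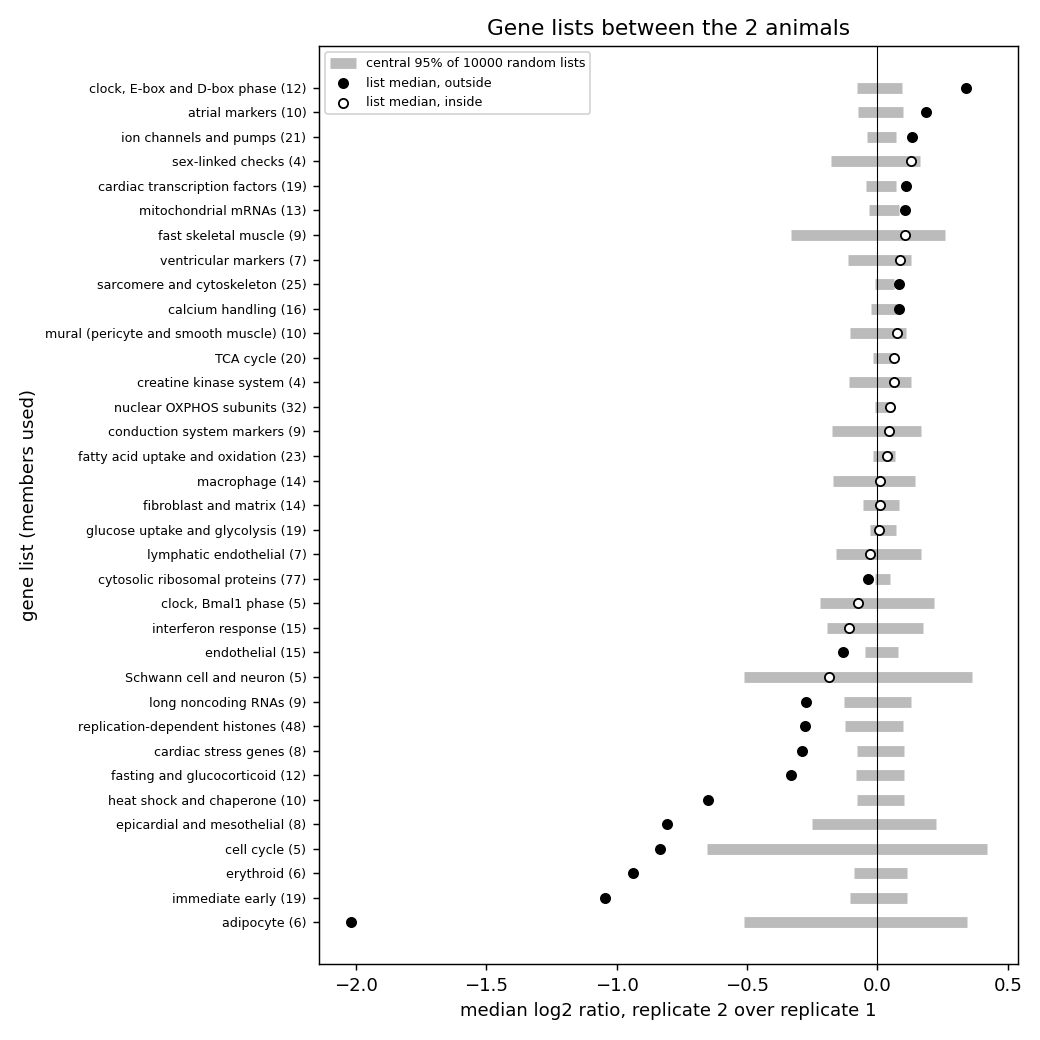
Median log2 ratio of replicate 2 over replicate 1 for 35 gene lists (points, filled when outside), with grey bars for the central 95% of 10000 random lists matched on expression. Immediate early genes lie at -1.05 and the E-box and D-box clock genes at 0.34, on opposite sides of their grey bars.

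The 2 quantifications ranked genes alike within a library. Across 55450 genes, Spearman's rho of log2(TPM + 1) was 0.910 in replicate 1 and 0.909 in replicate 2, and Pearson's r was 0.972 in each. Genes are not independent replicates, so these describe the tables only. Between the animals, rho was 0.983 over the 11607 genes at 1 TPM or more in both.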

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

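Reads of the phiX control genome, which the comparisons above do not use, were counted in both libraries at 62 in replicate 1 and 60 in replicate 2. Both lie above the 3 counts that a count of 0 allows. No explanation was tested for them.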

How the results depend on the processing

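No paired analysis was possible because the series holds 1 group. The 2 alternatives for the mitochondrial share (with pseudogenes, with ribosomal RNAs) and the count of genes passing in both quantifications were chosen after seeing the data. The count of detected genes kept within 1.5 times except at 5 TPM (7267), and was 11954 to 12047 from single libraries. The mitochondrial share was 12.2% of expected counts, 30.5% among protein-coding genes, 22.8% with pseudogenes and 36.4% with ribosomal RNAs, which follows from what each counts, and 15.3 to 16.5% in single libraries. The 100 most abundant genes held 36.6% among nuclear protein-coding genes and 74.4% in the second quantification (72.8 to 73.4% in single libraries). Spike-ins held 0.182% of the second quantification's counts, and 0.203 to 0.213% in single libraries. The cause of the shifts in the second quantification was not tested.

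Counts of lists above 1 TPM (33, range 32 to 35), of pairs led by the first gene (21 throughout) and of isoform shares over 50% (7, range 6 to 9) stayed within 1.5 times. Genes differing between the animals numbered 111 to 120 under 4 other scalings. Without the count filter there were 470 (357 higher in replicate 1, 113 in replicate 2), at 1000 counts 28 (25 and 3), at 1.5-fold 387 (276 and 111) and at 4-fold 32 (28 and 4), as those thresholds set. The 118 genes all remained under TMM without mitochondrial genes, 116 under DESeq2 size factors, 115 under spike-in scaling, 111 under total counts and 94 in the second quantification. In the second quantification the ratios of Gm2004, Gm28635 and Mrpl23 fell below 2-fold, and Scgb1a1 fell below the count minimum. The coefficient of variation ranged from 0.119 to 0.148, but the median of DESeq2 gene-wise estimates was 1e-04, its lower bound. Lists outside the central 95% were the same 19 of 35 in the second quantification and under the scalings, which move all genes alike and can hardly change these percentiles. With 200 summed counts 17 of 31 lists lay outside, 16 of them among the 19. The adipocyte and cell cycle lists then had too few members, the histones reversed to 0.0775 with fewer members, and the Bmal1-phase list came in at -0.39. The quantifications' Spearman's rho was 0.980 over genes at 1 TPM in both, and Pearson's r 0.981 there and 0.968 with a pseudocount of 0.1, against 0.910 and 0.972, and the cause was not tested. Among single lists, pairs, genes and isoforms, 323 values stayed the same, 132 moved by over 1 SD, 4 weakened, 1 strengthened and 1 reversed, single-library values not counted. The depth of 39.98 to 42.05 M counts limits genes with few reads, and the recovery of 2-fold differences under 200 summed counts was not simulated.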

Other observations

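Genes outside the fixed lists also met the rule for differing genes. They were picked here after their values were seen. Of genes that encode complement proteins, C3 was at a log2 ratio of -1.14 (8590 and 3767 counts), Cfb at -1.77, Cfp at -2.65 and C4b at -2.38, although C4b shares sequence with C4a. The complement genes C1qa, C1qb and C1qc did not meet the rule, with C1qa at 0.26, C1qb at 0.07 and C1qc at 0.13. The integrin genes Itgb2 (-2.97) and Itgam (-2.74) met it as well, as did Thbs1 at -2.31 and Prg4, a lubricating protein of joint and serosal surfaces, at -2.01. In replicate 2, 957 reads lay on Gm24497 and 212 on Gm14760, against 0 on each in replicate 1, and Pgk1-rs7 had 7 and 195 counts. Gm24497 and Pgk1-rs7 were listed at 0 in the second quantification, where Gm14760 had a log2 ratio of -0.94, so none of the 3 is read as a difference between the animals.

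In the 3 patterns below, the tests of a whole-lung library, of resident macrophages, of library scaling and of time of day were chosen after the values they use had been seen. The gene lists for airway epithelium, serous cavity macrophages and alveolar macrophages were written after the genes that differ most were known but before their own members' values were examined. The labels put both animals in 1 group, so no biological explanation given by the design was tested.

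Airway secretory genes were read in replicate 1 and almost absent from replicate 2. Reads of a whole-lung library are argued against, since Sftpc, among the most abundant lung transcripts, had 0 reads in replicate 1 (upper 95% limit 3.69) against 204 for Scgb1a1. A candidate explanation is airway epithelium in the dissected tissue. Of 16 other airway genes, 7 had 20 or more summed reads and 5 were higher in replicate 1 beyond the counting interval, among them Cyp2f2 (121 and 5 reads), Muc5b (39 and 0), Scgb3a2 (37 and 0) and Sec14l3 (37 and 0). In replicate 2, 2 of the 16 genes passed 1 TPM (Tppp3 and Cbr2), and the 16 genes together held 1013 counts in replicate 1 and 472 in replicate 2.

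Some macrophage-associated genes, such as Alox15, Chil3 and Lyz2, were at least 2-fold higher in replicate 1. The fixed macrophage list was not, with a median log2 ratio of 0.01 and 2 of 14 members meeting the rule for differing genes. Medians of the neutrophil (1.11 against 0.210 TPM) and lymphocyte (0.460 against 0.130) lists were higher in replicate 1 too. Both lists had too few members with enough reads for a comparison with random lists. The resident macrophage genes C1qa, C1qb, C1qc, Csf1r, Mrc1, Cd163, Folr2 and Cd68 had a median log2 ratio of 0.10. Their intervals had a lowest bound of -0.79, above the -1 of a 2-fold rise. From the same fixed list, Lyz2 (-1.62) and Adgre1 (-1.35) were higher in replicate 1. A larger share of resident heart macrophages is therefore left undecided, since these genes were chosen after their values were seen. Serous cavity macrophages in the dissected tissue may contribute: 7 of 11 genes of a separate list were higher in replicate 1 beyond the interval, including Serpinb2 (159 and 1 reads), Padi4 (120 and 7), Saa3 (51 and 2) and Cd5l (36 and 0). In replicate 2, 3 of the 11 passed 1 TPM, Vsig4 had 10 and 27 reads, and Padi4 and Saa3 are also made by other cells. Of the 11 genes, 10 had 20 or more summed reads. Together the 11 held 2800 counts in replicate 1 and 1450 in replicate 2, a smaller gap than that of the genes named. Alveolar macrophages cannot be told apart as a further source, because only 1 of 7 genes (Plet1, 38 and 13 reads) had enough reads, and its interval excluded 1.

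Immediate early and heat shock genes were higher in replicate 1. Library scaling moves all genes alike and can hardly set these lists apart from random lists matched on expression, where both lay at percentile 0. That follows from how the percentile is computed and is no independent test. Time of day at collection cannot be told apart from other explanations. The E-box and D-box clock list lay at percentile 100 of random lists, as a difference in time could give, but the Bmal1-phase list lay inside the central 95% at -0.07 (percentile 21.03). With members at 200 or more summed counts the latter moved below it, to -0.39 (percentile 0.25), over 4 genes that include Nfil3 at -1.15.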
